A study of Homo sapiens with 8 samples.

How the data were processed

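RNA from whole cultures of HUES6, an established human embryonic stem cell line, was measured on 8 Illumina BeadChip arrays, 4 labelled wildtype and 4 labelled VGLL4 overexpression. The labels describe the cells as grown on irradiated mouse embryonic fibroblasts, which serve as feeder cells, so the RNA came from cultures that held both. Per the labels, the VGLL4 cells had received a lentivirus with the open reading frame of human VGLL4, and no virus is named for the wildtype cells. The groups were taken from the sample titles. The labels call the 4 samples of each group biological replicates. The file headers name 1 chip, in columns that matched no sample label, so chip could not be tested as a batch.

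The values used were the deposited linear probe intensities of the 8 samples, for 47323 probes. BeadStudio is named in the submitters' processing notes, without a version. The deposited intensity values had been scaled by the authors to a mean of 217 on every array, and they ran from 22.4 to 17054 with no background subtracted. A further 80 columns of signals, bead statistics and detection p-values in the other tables were not used, because their column names matched no sample label. The planned background correction with negative controls or detection p-values, and the planned filter on detection, could therefore not be run on these samples. The fallback written in the plan was used instead: log2 of the deposited intensity, quantile normalization, and no filter. Without background subtraction, folds are compressed, most of all for dim genes.

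Probes were named by the annotation deposited with the series: 44053 probes carried 1 of 31426 gene symbols, and 3270 carried none. A reference table of human genes (assembly GRCh38.p14, used for names alone) gave current symbols for 27607 of the named probes, of which 4069 differed from the older symbol. Symbols are printed as deposited, such as CTGF and CYR61 for the genes now named CCN2 and CCN1. The files name no genome build, so chromosomes are given without positions.

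Each probe was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with group as the sole term. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 47323 probes, with a threshold of 0.05. A gene was represented by its probe with the highest mean signal, and all levels and changes are on the log2 scale, as VGLL4-labelled minus wildtype. The SE of a gene's change is the moderated SE of limma, which draws on the spread of probes of similar intensity. It can therefore be smaller than the spread between that gene's own arrays would give. The SE of a list or family mean is the plain SE between arrays. FKBP14 was the 1 gene with called probes in opposite directions. Background was taken from 446 probes for olfactory receptor genes, none of which was called: a probe counted as above background on an array when it exceeded their 95th percentile there. A gene at background on all arrays of 1 group is given as at least N-fold, with that percentile as the floor, and no fold is given where both groups were at background.

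Gene lists were fixed before the data were examined. There were 30 lists with 820 distinct genes. Each was tested by limma camera against all other genes, with a preset correlation between genes of 0.01, adjusted over the 30 lists. Some genes stand on several lists, so list results are not all separate observations. The YAP/TEAD and Hippo lists shared 6 genes, the pro-apoptotic and p53 lists 5, and the WNT and TGF-beta lists 4. The genes named in the text were chosen by a rule fixed before the data were examined: the 12 largest rises and 12 largest falls among called genes whose groups did not overlap and whose symbol was no placeholder, up to 4 members of each list with the smallest p, and a fixed set of 15 genes (VGLL4, POU5F1, NANOG, SOX2, CTGF, CYR61, YAP1, TEAD1, BCL2, BCL2L1, BIRC2, BIRC3, XIAP, CDH1 and ROCK1). Genes outside that rule are marked where they are named. The results of 1 list and of 1 named gene are not reported here.

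The steps were tested on simulated arrays drawn from the means and spreads of these 47323 probes, with 50 probes changed at each size. The changed probes were picked among those above the median signal, so recovery of dimmer probes was not tested. Of changes of 1 on the log2 scale, 96.0% of falls and 94.0% of rises were recovered, and of changes of 0.5, 32.0% of falls and 38.0% of rises. There were 4 false calls among 134. A simulated list shifted by 0.3 was called, and 0 of 29 other lists were. Simulated genes varied independently, so this does not show how often lists whose genes vary together would be called falsely. The number of arrays limits the precision.

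Alternatives planned before the data were examined were median scaling, the authors' scaling alone, the replicate number as a block, array weights, no intensity trend, each array left out, the mean of all probes of a gene, an estimated correlation in camera, limma's fry test and a minimum fold of 1.2. Background correction by neqc with the olfactory receptor probes as negative controls, a filter on background, and lists without fibroblast members were added after the data were seen.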

Results

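Signals of 47323 probes were compared between 4 arrays of wildtype HUES6 human embryonic stem cells and 4 arrays of the same line labelled VGLL4 overexpression. VGLL4 is a cofactor that binds TEAD transcription factors and competes with YAP for them, and the series title links it to the survival of embryonic stem cells. The question was which transcripts differed between the cultures. The median deposited intensity was 82.8 to 96.1 on the wildtype arrays and 73.1 to 85.1 on the VGLL4-labelled arrays, and 12706 to 15616 probes per array lay above background. Pairwise correlations between arrays were 0.968 to 0.979, and no 2 arrays held identical values. The first principal component held 21.5% of the variance and separated the groups, with wildtype replicate 4 farthest out.

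The signal of VGLL4 itself did not rise. Its 1 probe, for the gene on chromosome 3, read 7.90 ± 0.09 (SD, n = 4) on the wildtype arrays and 7.53 ± 0.17 (SD, n = 4) on the VGLL4-labelled arrays, a difference of -0.37 (SE 0.11) that did not pass the threshold by limma (adjusted p = 0.116). The position of the probe in the transcript is not given in the sources used here. Since the virus carried the open reading frame alone, a probe outside it would not read the transgene. The arrays therefore do not show whether the transgene was expressed, and every direction below is that of the VGLL4-labelled arrays against the wildtype arrays.

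Between the groups, 366 of 31426 genes changed, 158 higher and 208 lower on the VGLL4-labelled arrays. All 26 genes that changed by 2-fold or more in this fit were lower. HAND1, a transcription factor of heart and extraembryonic mesoderm on chromosome 5, fell by 2.23 (SE 0.26), or 4.69-fold. Its VGLL4-labelled arrays spread widely, at 8.30 ± 1.02 (SD, n = 4), with replicate 1 at 9.79. Type III collagen COL3A1 on chromosome 2 fell by 2.18 (SE 0.26), and the imprinted noncoding RNA H19 on chromosome 11 fell by 2.13 (SE 0.28). For COL3A1 and H19 the wildtype arrays spread widely, with SDs of 0.96 and 0.93. The membrane protein gene TM4SF1 fell by 1.89 (SE 0.11), and the matrix genes TGFBI, COL1A1 and HAPLN1 changed by -1.55, -1.54 and -1.5. CDH11, a cadherin of mesenchymal cells, fell by 1.49 (SE 0.14). Also among the 12 largest falls were CYR61, IGFBP3 and EMP1, the last at background on the VGLL4-labelled arrays and so at least 2.17-fold lower.

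Rises were smaller, the largest being 0.94 (SE 0.12) for METTL7A, a methyltransferase gene on chromosome 12. The AP-1 transcription factor genes FOS and FOSB rose by 0.90 (SE 0.12) and 0.77 (SE 0.12). THBS2, a matrix glycoprotein gene, rose by 0.89 (SE 0.13), SHISA2 by 0.81 (SE 0.13) and the zinc finger gene ZSCAN2 by 0.77 (SE 0.10) at 1 of its 4 probes, a call that ended with the mean of its probes (0.39, adjusted p = 0.0846). That no rise reached 2-fold depended on the setting: METTL7A, FOS and SHISA2 read 1.06, 1.06 and 1.00 with median scaling, and with neqc METTL7A, THBS2, FOSB, FOS, ZSCAN2 and SHISA2 read 1.34, 1.33, 1.16, 1.16, 1.09 and 1.03. LEFTY1, an inhibitor of NODAL signalling, rose by 0.65 (SE 0.08), and UTF1, a chromatin factor of pluripotent cells, by 0.69 (SE 0.13). The reductase gene AKR1C3, TNFRSF11B, which encodes osteoprotegerin, and SPRR3 were at background in wildtype and rose at least 1.23-fold, 1.22-fold and 1.05-fold. DPPA5 was called higher with both groups at background. By probe, 432 changed, 184 higher and 248 lower, and for 405 of these the groups did not overlap. Of all probes, 5.98% did not overlap, against 2.86% by chance. The split between directions depended on scaling: with arrays scaled to a common median, 302 probes were higher and 87 lower. The count fell to 282, 274 and 277 probes without VGLL4-labelled replicate 2, 3 or 4.

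**Figure D1:**
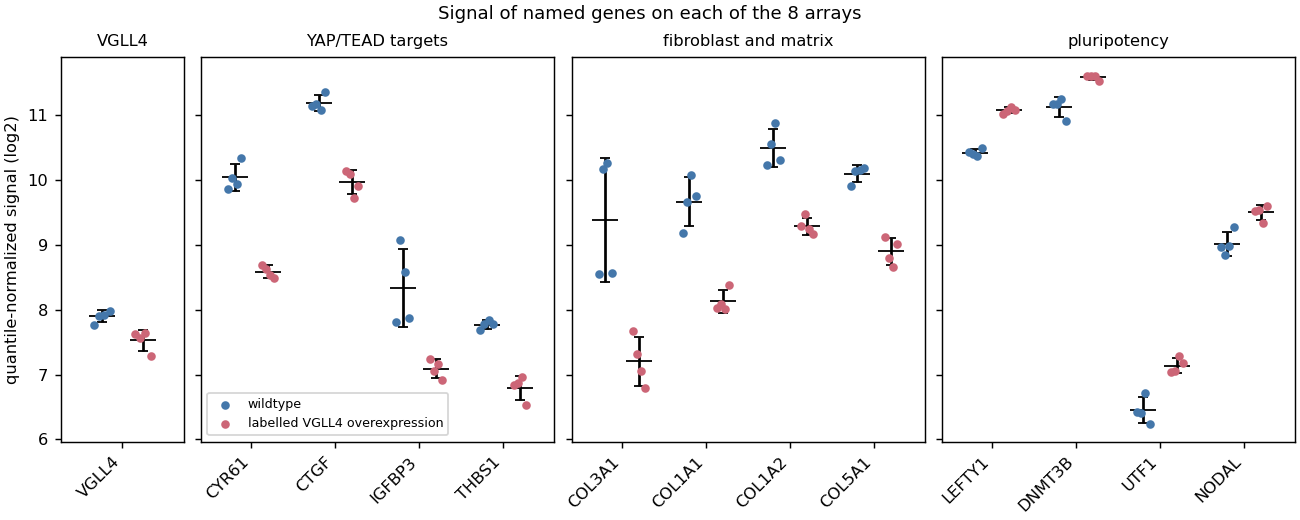
Quantile-normalized log2 signal of VGLL4 and of 4 genes each from the YAP/TEAD, fibroblast and pluripotency lists. Points are the 8 arrays by group, and the horizontal marks with bars are the mean and SD of 4 arrays. CYR61 read 10.04 in wildtype and 8.59 on the VGLL4-labelled arrays, while LEFTY1 read 10.42 and 11.08.

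Target genes of YAP and TEAD were lower as a group. Of 33 measured, 8 fell, 0 rose and 25 did not pass, and adjusted over the list alone 10 fell. CYR61 and CTGF, matricellular protein genes widely used as readouts of YAP, fell by 1.46 (SE 0.10) and 1.22 (SE 0.10), or 2.74-fold and 2.33-fold. IGFBP3, which binds insulin-like growth factors, fell by 1.24 (SE 0.18), and THBS1, encoding thrombospondin, by 0.98 (SE 0.11). ANKRD1, AXL and FJX1, outside the naming rule, also fell. As a list they averaged -0.33 (SE 0.03), with a camera adjusted p of 4.94e-15, and 0.0127 with an estimated correlation. That mean was -0.22 with median scaling and -0.50 with the filter on background, above which 20 of the 33 genes lay.

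Components of the Hippo pathway moved less. Of 37, 2 fell and 0 rose, 5 fell adjusted over the list alone, and the list mean was -0.09 (SE 0.02; camera adjusted p = 0.00271, and adjusted p = 0.0471 with an estimated correlation). FRMD6, an upstream regulator of the pathway, fell by 0.53 (SE 0.11), a call that ended without 1 of the 8 arrays, VGLL4-labelled replicate 3 (adjusted p = 0.0549). TEAD4, a TEAD factor, fell by 0.41 (SE 0.10) at 1 of 3 probes, and its call ended without any 1 of 5 arrays (adjusted p up to 0.126). YAP1 read -0.15 (SE 0.13) and did not pass, and TEAD1 was at background in both groups. Median scaling ended the call of this list (mean -0.002, adjusted p = 0.0823) and those of FRMD6 and TEAD4 (adjusted p = 0.251 and 0.617).

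Markers of fibroblasts, the cell type of the feeder layer, were lower on the same arrays. Of 34 measured, 14 fell, 1 rose and 19 did not pass, and adjusted over the list alone 22 fell and 1 rose. Besides COL3A1, COL1A1 and TGFBI, the collagen genes COL1A2 and COL5A1 fell, to 9.29 and 8.90 from 10.50 and 10.10 in wildtype. The gene that rose was THY1, a surface protein gene of fibroblasts and of pluripotent cells, chosen after its value was seen, by 0.62 (SE 0.09). The list mean was -0.55 (SE 0.07), with a camera adjusted p of 1.1e-32, and 0.0134 with an estimated correlation, and -0.39 with median scaling. The wildtype arrays spread widely for COL3A1, at 9.39 ± 0.96 (SD, n = 4), and less for COL1A1, at 9.67 ± 0.37 (SD, n = 4).

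**Figure D2:**
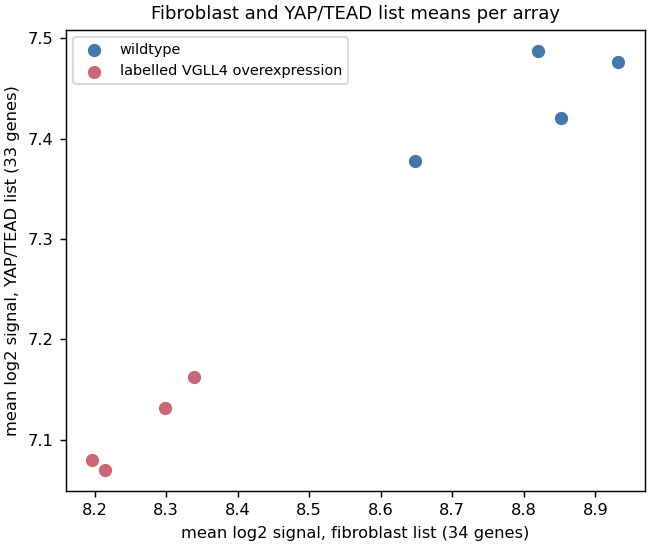
Mean log2 signal of the 34 fibroblast genes (x axis) against that of the 33 YAP/TEAD genes (y axis), 1 point per array, coloured by group. The wildtype arrays lie at 8.65 to 8.93 and 7.38 to 7.49, and the VGLL4-labelled arrays at 8.20 to 8.34 and 7.07 to 7.16.

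Several lists of mesenchymal, contractile and matrix genes fell along with the fibroblast list. Of 26 targets of SRF and its cofactors, 8 fell and 1, FOS, rose, with 15 falls and 1 rise adjusted over the list alone. The cardiac actin gene ACTC1 fell by 1.03 (SE 0.12) at 1 of 2 probes, caldesmon CALD1 by 0.84 (SE 0.09) and tropomyosin TPM1 by 0.72 (SE 0.09). Their mean was -0.30 (SE 0.09; camera adjusted p = 7.89e-16, and adjusted p = 0.07 with an estimated correlation), and -0.09 with median scaling. Of 30 integrin and matrix genes, 4 fell, 9 adjusted over the list alone. CD44, a hyaluronan receptor, fell by 1.09 (SE 0.10) at 1 of 3 probes, laminin LAMA5 by 0.58 (SE 0.09) and integrin ITGB1 by 0.54 (SE 0.09) at 2 of 6 probes. Their mean was -0.17 (SE 0.04; camera adjusted p = 6.7e-07, adjusted p = 0.0471 with an estimated correlation, and adjusted p = 0.096 with median scaling, where the mean was -0.01). Median scaling also ended the calls of TPM1, LAMA5 and ITGB1 (adjusted p = 0.125, 0.304 and 0.398). With the mean of all probes of a gene the calls of ACTC1, CD44 and ITGB1 ended (-0.41, -0.41 and -0.21, adjusted p = 0.0695, 0.0729 and 0.386).

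Of 30 mesoderm and primitive streak genes, 5 fell and 1 rose, and adjusted over the list alone 8 fell and 3 rose. HAND1 and the growth factor gene BMP4, which fell by 1.00 (SE 0.12) at 1 of 3 probes (-0.38 over all its probes, adjusted p = 0.117), were among them, as was the growth factor receptor gene PDGFRB, at background on the VGLL4-labelled arrays and at least 1.14-fold lower. The list mean was -0.25 (SE 0.08; camera adjusted p = 9.63e-05, and adjusted p = 0.0802 with an estimated correlation), and -0.17 with median scaling. Among 26 trophectoderm genes, 2 fell, HAND1 and IGFBP3, also when adjusted over the list alone (mean -0.19, SE 0.03, camera adjusted p = 0.00432, and adjusted p = 0.0565 with an estimated correlation). HAND1 is also on the mesoderm list and IGFBP3 on the YAP/TEAD list, so these falls are not separate from those. With the filter on background the trophectoderm mean was -0.61, but only 7 of the 26 genes lay above background, HAND1 and IGFBP3 among them. With median scaling the mean of the list was -0.13. Of 28 genes responding to TGF-beta, NODAL or BMP, 7 fell and 3 rose, with 9 falls and 5 rises adjusted over the list alone. The falls included TGFBI, BMP4 and BAMBI, a decoy receptor, which fell by 0.82 (SE 0.11). The 3 rises were LEFTY1, NODAL and CER1, which are ligands or secreted inhibitors of the NODAL branch, CER1 losing its call without any 1 of 6 arrays (adjusted p up to 0.159). The list mean was -0.22 (SE 0.04; camera adjusted p = 7.76e-05, adjusted p = 0.0446 with an estimated correlation, and adjusted p = 0.0682 with the authors' scaling, where the mean was -0.22), and -0.06 with median scaling. Of 30 WNT targets, 3 fell, CD44, BAMBI and the cyclin gene CCND1, and 8 fell and 2 rose adjusted over the list alone. Their mean was -0.15 (SE 0.05, camera adjusted p = 0.000364, and adjusted p = 0.0968 with an estimated correlation). That mean was -0.04 under median scaling and -0.25 with the filter on background, above which 17 of the 30 genes lay. BAMBI and CCND1 lost their calls with median scaling (adjusted p = 0.085 and 0.482).

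Pluripotency genes were higher. Of 40 measured, 7 rose, 1 fell and 32 did not pass, and adjusted over the list alone 16 rose and 1 fell. LEFTY1 and UTF1 led, the latter above background on 1 of 4 wildtype arrays. The DNA methyltransferase gene DNMT3B rose by 0.46 (SE 0.09) at 3 of 5 probes, and NODAL, a ligand that maintains pluripotency, by 0.48 (SE 0.10). Both lost their calls without the intensity trend. The core factors gave smaller values that did not pass: POU5F1 0.30 (SE 0.09; adjusted p = 0.153), NANOG 0.32 (SE 0.10; adjusted p = 0.162) and SOX2 0.36 (SE 0.12; adjusted p = 0.214). The 1 fall, chosen after its value was seen, was that of LIN28, an RNA-binding protein gene, by 0.39 (SE 0.08). The list mean was 0.20 (SE 0.04; camera adjusted p = 7.44e-12, and adjusted p = 0.0228 with an estimated correlation), and 0.37 with median scaling.

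Genes of cell survival did not move as a group. Of 33 pro-apoptotic genes, 0 were called by limma, and 2 rose and 2 fell adjusted over the list alone (mean -0.001, SE 0.02; camera adjusted p = 0.88). Of 28 anti-apoptotic genes, BIRC3, an inhibitor of apoptosis gene, rose by 0.57 (SE 0.13) at 1 of 3 probes and BCL2L1, which encodes BCL-XL, fell by 0.36 (SE 0.08) at 1 of 2 probes, the same counts as adjusted over the list alone (mean 0.01, SE 0.01; camera adjusted p = 0.88). BIRC3 lost its call without any 1 of 5 arrays (adjusted p up to 0.143) and BCL2L1 without any 1 of 6 (adjusted p up to 0.124). BCL2 read 0.14 (SE 0.12) at the brightest of its 4 probes, above background on 1 wildtype array and on 4 VGLL4-labelled arrays. Its other probes read -0.35, -0.13 and -0.32, so its direction was not settled. BIRC2 read -0.17 (SE 0.11), and XIAP was at background in wildtype. BCL2, BIRC2 and XIAP did not pass. Of 28 p53 targets, GADD45A, a growth arrest gene, fell by 0.53 (SE 0.11) at 1 of 2 probes, and 5 fell and 1 rose adjusted over the list alone (mean -0.11, SE 0.03; camera adjusted p = 0.00262, adjusted p = 0.08 with an estimated correlation and 0.262 with median scaling, where the mean turned to 0.02, and 0.143 with the authors' scaling, where it was -0.14). GADD45A lost its call without either of 2 arrays (adjusted p up to 0.0673). The kinase gene ROCK1 read -0.05 (SE 0.15). Of 27 adhesion and junction genes, the nectin genes PVRL2 and PVRL3 changed by -0.53 and -0.42, calls that ended without any 1 of 2 and of 6 arrays (adjusted p up to 0.0642 and 0.157), 5 fell adjusted over the list alone, and E-cadherin CDH1 read -0.21 (SE 0.09; adjusted p = 0.44). That list's mean was -0.09 (SE 0.03; camera adjusted p = 0.00353, adjusted p = 0.0889 with an estimated correlation and 0.988 with median scaling, where the mean turned to 0.07, and 0.666 with the authors' scaling, where it was -0.09). BCL2L1, GADD45A, PVRL2 and PVRL3 lost their calls with median scaling (adjusted p = 0.797, 0.303, 0.299 and 0.649).

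Genes of amino acid supply and the unfolded protein response were lower: of 34, 3 fell, and 12 fell adjusted over the list alone. SLC7A5, a subunit of an amino acid transporter, fell by 0.68 (SE 0.11), its partner SLC3A2 by 0.45 (SE 0.09) at 1 of 3 probes and asparagine synthetase ASNS by 0.42 (SE 0.10) at 1 of 2. SLC3A2 and ASNS lost their calls without any 1 of 2 and of 5 arrays (adjusted p up to 0.0574 and 0.101). The list mean was -0.16 (SE 0.03; camera adjusted p = 5.2e-08, adjusted p = 0.0237 with an estimated correlation and 0.248 with median scaling, where the mean turned to 0.02). Of 33 hypoxia and glycolysis genes, 3 fell, with 7 falls and 1 rise adjusted over the list alone. The glucose transporter SLC2A1 fell by 0.70 (SE 0.09), and the list mean was -0.11 (SE 0.02; camera adjusted p = 0.0016, adjusted p = 0.0671 with an estimated correlation and 0.86 with median scaling, where the mean turned to 0.06, and 0.575 with the authors' scaling, where it was -0.10). Of 24 immediate early genes, FOS and FOSB rose and CYR61 and IER3 fell, IER3 losing its call without any 1 of 4 arrays (adjusted p up to 0.139), with 2 rises and 7 falls adjusted over the list alone (mean -0.09, SE 0.05; camera adjusted p = 0.0089, and adjusted p = 0.231 with an estimated correlation, 0.549 with median scaling, where the mean turned to 0.04, and 0.38 with the authors' scaling, where it was -0.11). Without wildtype replicate 2 or VGLL4-labelled replicate 4 that list's adjusted p was 0.0592 or 0.0578. Median scaling ended the calls of SLC7A5, SLC3A2, ASNS, SLC2A1 and IER3 (adjusted p = 0.15, 0.558, 0.611, 0.135 and 0.577).

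Lists of growth were slightly higher with few or no single genes called. The mean was 0.10 (SE 0.02) for 34 genes of oxidative phosphorylation, of which the complex I gene NDUFA8 rose by 0.36 (SE 0.09), as it did adjusted over the list alone, a call that ended without any 1 of 6 arrays (adjusted p up to 0.175). The mean was 0.10 (SE 0.03) for 30 genes of DNA replication and 0.09 (SE 0.03) for 32 of mitosis, with 0 called by limma in either, also adjusted over the list alone. The camera adjusted p was 0.000364, 0.00121 and 0.00262, and the adjusted p with an estimated correlation was 0.0694, 0.0834 and 0.106. With median scaling these means were 0.33, 0.29 and 0.29, where probes above background shifted by a median of 0.16. MCM4, a helicase subunit gene, read 0.26 (SE 0.09), and AURKB, a mitotic kinase gene, 0.32 (SE 0.10). Of 19 histone genes 0 were called, and 3 rose adjusted over the list alone (mean 0.14, SE 0.05; camera adjusted p = 0.00353, and adjusted p = 0.231 with an estimated correlation), with a mean of 0.24 under median scaling and 0.06 with the filter on background.

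The remaining lists did not pass. They were neural ectoderm (34 genes, mean -0.06, camera adjusted p = 0.279), endoderm (24 genes, mean -0.0007, adjusted p = 0.753), interferon response (35 genes, mean -0.04, adjusted p = 0.306), heat shock (20 genes, mean -0.03, adjusted p = 0.88), cholesterol synthesis (24 genes, mean 0.02, adjusted p = 0.848), ribosomal proteins (40 genes, mean -0.02, adjusted p = 0.409), mature neuron (18 genes, mean 0.06, adjusted p = 0.366) and housekeeping genes that mark RNA quality (20 genes, mean 0.01, adjusted p = 0.88). Mean and median differed in sign for endoderm, heat shock, mature neuron and both apoptosis lists. Single genes were called in some of these lists. SOX3, a neural and pluripotency factor gene on the X chromosome, fell by 1.08 (SE 0.12), the interferon-induced RNA sensor IFIH1 by 0.83 (SE 0.13) and the chaperone gene HSPA2 by 1.02 (SE 0.12). With median scaling the cholesterol and housekeeping lists passed as higher (adjusted p = 0.00734 and 0.00389), as they did with the authors' scaling. Heat shock and ribosomal proteins turned and passed as higher under both, at 0.17 and 0.18 with median scaling (adjusted p = 0.0407 and 0.00282) and 0.01 and 0.02 with the authors' scaling (adjusted p = 0.0114 and 0.00288). Under both scalings, probes above background stood higher than all probes, at medians of 0.16 against 0.06 and 0.01 against -0.10. Neural ectoderm passed as lower with the filter on background (mean -0.31, camera adjusted p = 0.014), and mature neuron as higher by fry (adjusted p = 0.036). Only 6 of the 34 neural ectoderm genes lay above background, so that call does not cover the whole list.

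**Figure D3:**
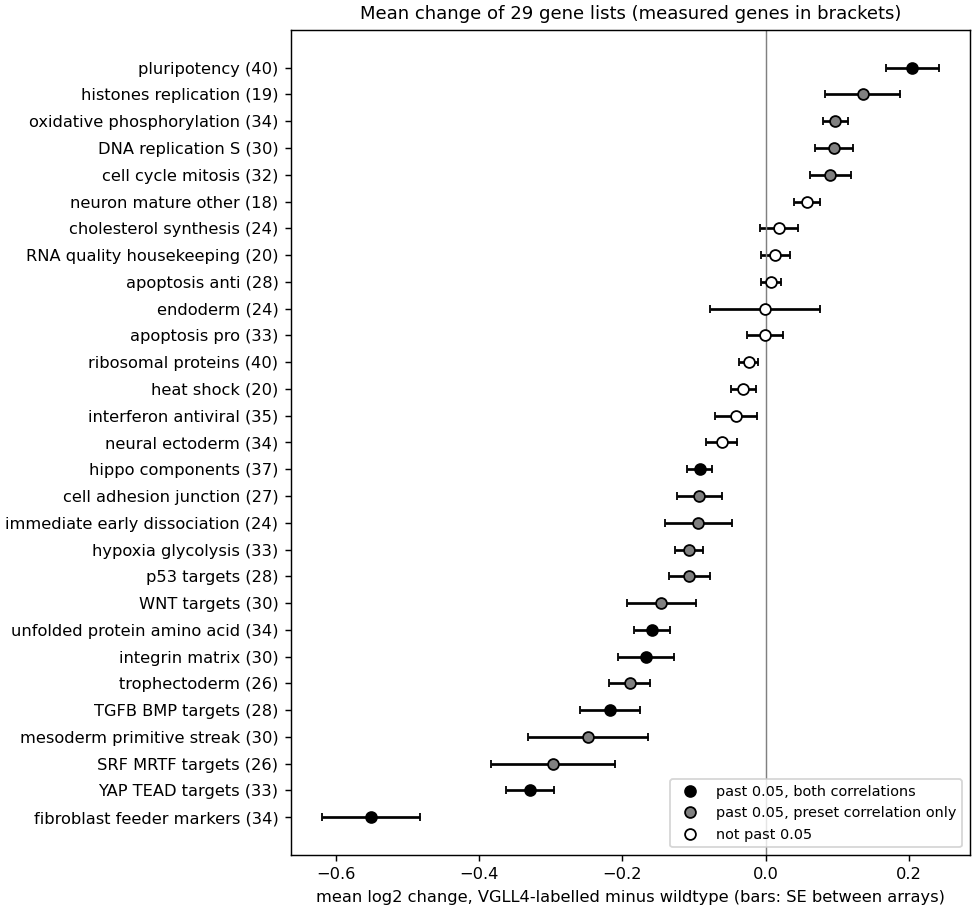
Mean log2 change of 29 gene lists, VGLL4-labelled minus wildtype, with the SE between arrays as bars. Black points passed 0.05 with both correlations (7 lists), grey points with the preset correlation alone (12 lists) and white points did not pass (10 lists). Fibroblast markers lie lowest, at -0.55, and pluripotency genes highest, at 0.20.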

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

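The tests of collagen-type members and of a shared factor for the pluripotency genes were chosen after the result was seen, and so were the comparisons with random and other lists and the adjustment for the fibroblast mean. All others in this part were written before.

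Of 330 groups of 4 arrays examined (named genes, list means and the deposited median), 25 held an array far outside the range of the other 3, where chance gives about 1 in 20. Wildtype replicate 4 was that array in 8 of them: BMP4 at 9.24, ANLN at 7.92, LAMC1 at 10.39, BCL2L1 at 10.72, CCNB2 at 9.13, SPRR3 at 6.12, METTL7A at 6.58 and the p53 list at 7.69. The other wildtype cases were ACTC1 at 11.48, HHEX at 6.39 and ZSCAN2 at 7.28 in replicate 1, TFAP2A at 7.15 and CRABP1 at 8.47 in replicate 2, and IFITM1 at 10.31 and the cholesterol list at 8.35 in replicate 3. Among the VGLL4-labelled arrays, replicate 1 stood apart for AFP at 9.43, CER1 at 10.09, the mesoderm list at 6.94 and the TGF-beta list at 8.06, and replicate 4 for YAP1 at 8.44, KIF11 at 8.37, DNMT3B at 11.53 and THBS2 at 7.39. EBP stood apart at 7.85 in replicate 2 and CDH1 at 10.15 in replicate 3.

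The lower YAP/TEAD targets were weighed against 2 technical explanations. The tables argue against scaling as the cause: the list mean stayed over 2 SE below 0 under the authors' scaling, median scaling and background correction, the ratio of mean to SE nearest 0 being -3.87. A smaller carry-over of feeder fibroblasts, or of fibroblast-like human cells, remains a candidate explanation, because the YAP/TEAD and fibroblast means rose and fell together within the groups. Over the 8 arrays r was 0.822 (permutation p = 0.0243, one-sided, 576 orders within groups), Spearman's coefficient 0.762 (permutation p = 0.0365) and r 0.72 without the 2 arrays farthest out. That r was unusual among random lists, 1.19% of 10000 being as high. Adjusted over 29 lists, however, its permutation p was 0.352. Given the fibroblast mean, the YAP/TEAD change was -0.11 (SE 0.07). However, the fibroblast mean itself separated the groups, at 8.65 or more in wildtype and 8.34 or less on the VGLL4-labelled arrays. With 8 arrays this adjustment therefore cannot tell how much of the fall goes with fibroblast content and how much with group. An effect of VGLL4, or of transduction, on YAP/TEAD targets stays open and untested.

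For the fibroblast genes themselves, 11 of 12 collagen-type members above background in wildtype were lower after background correction. Their changes ran from -2.71 to 0.01 and did not share a common value (exact permutation p = 0.0286 over the 35 splits of the arrays, the smallest they can give). A smaller share of feeder cells would lower all their transcripts by a like amount. However, human cells may add to the same signals, and human probes may read mouse transcripts to different degrees. The part of a signal that came from feeder cells may thus differ between genes. The spread therefore does not decide, and feeder share cannot be told apart from a change in the human cells.

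For the higher pluripotency genes, the tables argue against scaling as the cause, since the list mean stayed at least 3.41 SE above 0 under the same 3 settings. That lowest ratio came from median scaling, which tests little, as it also shifted probes above background by a median of 0.16. With the authors' scaling and background correction that shift was 0.01 and 0.02, and the list mean lay 4.61 and 6.06 SE above 0. The 30 members above background spread from -0.40 to 1.00 after correction (exact permutation p = 0.0286 over the same splits, the smallest they can give). That spread and the fall of LIN28 argue against 1 common factor for every member. They do not decide on a larger share of undifferentiated cells, since members that other cells in the culture also express need not rise alike. Changes of single genes within the stem cells may add to a change in cell share, as a hypothesis, and both together were not tested.

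The counts argue against chance assignment of arrays but cannot exclude it, since 1 in 35 is the smallest share that the splits can give. Of the 35 ways to split the 8 arrays into 4 and 4, 1, the real one, gave as many as 432 probes, and the highest other gave 7. For lists, 1 of 35 gave as many as 19, and the highest other gave 13.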

How the results depend on the processing

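Background correction by neqc, the filter on background, and lists without fibroblast members were chosen after the data were seen. Detection p filters and chip as a block were not run, for lack of matched columns and with 1 chip named in the headers. No background correction and no filter were the settings used. No named gene that was called changed direction under any alternative that was run. Of 69 named calls, 46 held with each array left out in turn, 46 with median scaling, 57 with the authors' scaling, 62 with neqc, 43 without the intensity trend and 49 with the mean of all probes. VGLL4 stayed between -0.50 and -0.19, and passed in 1 setting, the filter on background (-0.37, adjusted p = 0.0357), where fewer probes were tested.

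Array weights and the authors' scaling left each count within 1.5 times. The authors' scaling moved the median of all probes by -0.10. Median scaling gave 302 probes higher and 87 lower (262 and 69 genes), while probes above background shifted by a median of 0.16, and 267 of the 432 probes kept their call. Without the intensity trend 163 probes (46 higher, 117 lower) and 135 genes (37 and 98) were called. With the mean of all probes, 204 genes (76 and 128) were called, and with a minimum fold of 1.2, 71 probes (8 and 63). The filter on background gave 702 probes (325 and 377) and 606 genes (286 and 320), as fewer probes were tested. Leaving out 1 array gave 274 to 396 probes (86 to 157 higher, 157 to 249 lower) and 232 to 331 genes (74 to 137 higher, 130 to 214 lower). With an estimated correlation 7 lists passed in place of 19. Of the 19, 12 held with median scaling, 14 with the authors' scaling and 17 with fry. With members of the fibroblast list taken out of the other lists, 19 held. The mesoderm and histone lists missed the threshold with the filter on background (camera adjusted p = 0.0958 and 0.568). There neural ectoderm, with 6 of its 34 genes above background, passed as lower (camera adjusted p = 0.014). By fry the histone and immediate early lists missed it (0.0688 and 0.126), and mature neuron passed as higher (0.036). Median scaling turned the mean of 5 passed lists, none of which passed there, to above 0: p53 (0.02), adhesion (0.07), hypoxia (0.06), amino acid supply (0.02) and immediate early (0.04). All other list means were also above their main values there. Both scalings turned lists that had not passed: heat shock passed as higher at 0.171 with median scaling and at 0.0144 with the authors' scaling, and ribosomal proteins at 0.179 and 0.0223. All 20 heat shock and 39 of 40 ribosomal genes lay above background. Probes above background shifted by a median of 0.163 with median scaling, against 0.0558 for all probes. With the authors' scaling these medians were 0.00616 and -0.101. Since camera compares a list with all other genes, a list of bright genes can pass as higher there without a rise of its own. Values near background limit the dim genes.

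The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.016, 0.006, 0.067 and 0.050. With the replicate block, 499 probes (192 higher, 307 lower) and 429 genes (167 and 262) were called, 413 of the probes shared with the fit without it, and 19 lists passed.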

Other observations

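The tests of all zinc finger genes, of HOX genes above background and of autosomes were written before their family values were seen, and those of zinc finger genes above background and of all HOX genes were not set beforehand. Moreover, the families were picked because called genes belonged to them. The metallothionein and imprinted genes were picked after their values were seen.

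Homeobox genes of the HOX clusters, which pattern the body axis, were lower. Over all 39 the mean was -0.16 (SE 0.04; camera p = 1.49e-06, and p = 0.0133 with an estimated correlation), 8 reading above 0, and it was -0.26 with the authors' scaling and -0.10 with median scaling. Of 7 above background, 4 fell and 0 rose: HOXB5 by 0.68 (SE 0.12), HOXA5 by 0.68 (SE 0.13), HOXB8 by 0.63 (SE 0.10) and HOXC8 by 0.56 (SE 0.12). The mean of the 7 was -0.46 (SE 0.12), and it stayed below 0 with the authors' scaling, median scaling and neqc (-0.46, -0.30 and -0.55). Camera gave p = 3.82e-11, and p = 0.0132 with an estimated correlation. The HOX genes may have fallen as a family, alongside the lower mesoderm and fibroblast genes.

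Of 158 genes that rose, 14 were ZNF-named zinc finger genes, 8 of them on chromosome 19, among them ZNF486 by 0.63 (SE 0.09) and ZNF430 by 0.61 (SE 0.11); 0 fell. The mean of all 526 ZNF-named genes was 0.0545 (SE 0.01; camera p = 0.00227, and p = 0.0322 with an estimated correlation), a small shift that turned to -0.04 with the authors' scaling, where the median of all probes was -0.10. For the 228 above background it was 0.09 (SE 0.02; camera p = 4.29e-06, and p = 0.00831 with an estimated correlation), with 13 higher and 0 lower, and 0.04 with the authors' scaling and 0.20 with median scaling. Extra copies of chromosome 19 are argued against by the 1334 genes there without a ZNF name, whose mean was 0.0107 (SE 0.01). No autosome's genes above background shifted by 0.1 or more, the farthest from 0 being chromosome 9 at 0.0277 (camera adjusted p = 0.844), which is in line with no whole-chromosome copy difference between the groups.

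Metallothionein genes of chromosome 16, which bind zinc and copper, were higher: 4 of 7 above background rose, MT1H by 0.63 (SE 0.10), MT1X by 0.61 (SE 0.08), MT1G by 0.58 (SE 0.09) and MT1F by 0.45 (SE 0.10), while MT2A read -0.01 (SE 0.11). Probes of these near-identical copies can read each other's transcripts, so they are not 4 separate observations. Imprinted genes moved unevenly: besides H19, DLK1 fell by 0.78 (SE 0.12), MEG3 of the same cluster on chromosome 14 rose by 0.55 (SE 0.10), and 9 others examined did not pass, IGF2 among them.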
